A study of Mus musculus with 4 samples.

How the data were processed

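The series holds 4 samples of mouse kidney cells, 1 each for angiotensin II hypertension, its saline control, salt-sensitive hypertension and its normal-diet control. Per the labels' protocols, kidneys were pooled within a group, dissociated, and selected with biotinylated antibodies to CD31 and then to podoplanin, and libraries were made with a droplet-based 3' kit. The submitters' processing notes name Cell Ranger 7.0.0, Seurat 4.1 and genome build mm10 without saying which step used which. The deposited tables hold whole-number UMI counts per gene and cell, not normalized, with no cell annotation. There are 4 tables: 1 for each hypertension library, 1 that joins both control libraries and 1 that joins both hypertension libraries. Tables were matched to groups by their names. In the control table the barcode ending separates 2 libraries, but no source used here says which model each belongs to, so they were summed. Whether counts of the control table were brought to a like depth on joining is not given in the sources used here. In the joined hypertension table the 3251 shared salt-sensitive cells have identical counts, while the 2727 shared angiotensin II cells hold 88.2% of the UMIs of their own table, so the separate tables were used and the joined table served as an alternative. No table holds mitochondrial genes, and the fewest genes of any deposited cell were 347 in the angiotensin II, 296 in the salt-sensitive and 288 in the control table.

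The 11049 genes listed in all 3 library tables were used. They hold 98.7% of the angiotensin II, 99.0% of the salt-sensitive and 99.1% of the control UMIs. Genes outside this set, among them 5 of the 10 lymphatic markers, are not analysed here apart from the cells with a UMI of Pdpn or Reln. Of the gene lists used below, the set holds 5 of 25 chemokine genes and 18 of 32 NF-kB and acute inflammation genes. It also holds 11 of 18 leukocyte adhesion and 12 of 21 complement and coagulation genes. Medians of these lists describe the genes held and not the full lists. Gene positions come from an annotation of GRCm38, the assembly of mm10, in which 10973 of the 11049 symbols matched. Counts of genes with near-identical copies, such as the H2-Q and H2-T families or Hspa1a and Hspa1b, are uncertain, since how reads shared by copies were assigned is not given in the sources used here.

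Cells with at least 200 genes were kept, which removed 0 cells. The planned limit on mitochondrial UMIs could not act. Scrublet, run per library, marked 42 of 10535 cells (0.399%), which were removed. A caller that marks so few cells has not worked, so doublets remain in the data. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 14 clusters of 10493 cells, without integration of libraries. A cluster took the name of the class with most of its fixed markers among its top 50 genes by fold, with at least 3 detected markers, unless its top 10 genes spoke for another class, so names are rebuilt and can differ from the authors'. In this way 5 clusters were named. A class called endothelial-like joined the clusters with 3 endothelial markers among the top 50 genes and those in which at least 3 of the 4 genes Pecam1, Cdh5, Kdr and Tie1 reached 3 times their lower quartile over clusters. The latter threshold was set after the data were seen. It adds clusters 5 and 11, which hold 8.99% and 1.35% of angiotensin II, 19.4% and 1.92% of salt-sensitive and 2.09% and 0.137% of control cells. Clusters 0, 1 and 3, with markers of proximal and distal segments together, are called mixed tubule clusters and hold 53.0% of kept cells.

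UMIs were summed per class and library and scaled to equal totals (CPM) over the shared genes. A log2 ratio is that of CPM + 5, which understates the change of low genes. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval of the plain ratio of the sums, without the pseudocount, so for low genes it can lie beyond the ratio printed. Shares of cells have exact binomial intervals and CPM exact Poisson intervals. A count of 0 allows 3 counts. A gene list is described by the median log2 ratio of its members with 20 or more UMIs, its 95% interval over 1000 Poisson draws, and its percentile among 10000 random lists of equal size matched on expression. With 1 library per group no p-value was computed. The study's 3 comparisons are each hypertension library over the control and angiotensin II over salt-sensitive hypertension. Lymphatic-like cells were to be compared where 50 were found per library. None were named, so all endothelial-like cells were used, and next every class or cluster with 50 cells per library. Endothelial-like sums were 5592366 UMIs in angiotensin II, 4220077 in salt-sensitive and 433147 in control cells, so ratios over control are limited by the control. In simulated counts the intervals covered the true ratio for 96.0% of 9130 genes (angiotensin II over control), 96.3% of 8940 (salt-sensitive over control) and 95.6% of 9896 (between the models).

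The comparisons, the rule for named genes, the 18 gene lists, the 25 marker lists and most alternatives were fixed before the data were examined. Named genes are, per comparison and class, the 12 highest and 12 lowest log2 ratios among genes with at least 50 UMIs, at least 50 CPM in the higher library and a class CPM of at least 0.25 times that of every other named class, leaving out ribosomal, haemoglobin and clone-named genes. Members of the lists with a log2 ratio of 1 or more in either direction, at most 4 per list, and the lymphatic markers and Pecam1 were added. Some genes are set beside them in another class or comparison for the same gene's sake, and the tubule genes under other observations were chosen after their values were seen. The lists are MHC class II presentation, MHC class I presentation, interferon response, chemokines, leukocyte adhesion, NF-kB and acute inflammation, endothelial junctions, lymphangiogenesis and lymphatic identity, vasoactive mediators, mineralocorticoid and sodium handling, extracellular matrix and TGF-beta, hypoxia and glycolysis, oxidative phosphorylation, fatty acid uptake and oxidation, oxidative stress, dissociation and immediate early genes, apoptosis and p53, and complement and coagulation. Alternatives changed the cell filter, doublet removal, clustering resolution, normalization, pseudocount, minimum UMIs, depth per cell (1000 UMIs), control libraries and the definition of the class.

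Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 (which ran Scrublet), anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.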

Results

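Kidney cells of C57BL/6J mice aged 10 to 14 weeks were profiled by droplet-based single-cell RNA sequencing in a pair of hypertension models. In the angiotensin II model the pressor hormone was given to induce hypertension and control mice received saline. In the salt-sensitive model the control mice ate a normal diet. Kidneys were pooled within each of the 4 groups. Cells were then taken with magnetic beads carrying antibodies to CD31, an endothelial surface protein encoded by Pecam1, and next to podoplanin, a protein of lymphatic endothelium and some epithelial cells. The study asked how hypertension alters lymphatic endothelial cells of the kidney and whether the models differ. Each group is 1 library without replicates, so the intervals given cover counting error only and no difference was tested. The angiotensin II library held 2837 cells and 7479337 UMIs (unique molecular identifiers, each standing for 1 captured transcript), and the salt-sensitive library held 3284 cells and 6471741 UMIs. The control libraries held 2406 and 2008 cells with 2801925 and 1727731 UMIs. Which of them belongs to which model is not given in the sources used here, so they were summed as a common control. Median UMIs per cell were 1795 in the angiotensin II library, 1785.5 in the salt-sensitive library, 973 in control library 1 and 557 in control library 2.

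The hypertension libraries were rich in endothelial cells, whereas most control barcodes carried kidney tubule transcripts. Endothelial-like cells made up 45.6% of the angiotensin II library (95% exact binomial interval 43.7 to 47.5, 1288 of 2825 kept cells). They made up 52.1% of the salt-sensitive library (50.4 to 53.8, 1706 of 3273 cells) and 4.78% of the control (4.17 to 5.45, 210 of 4395 cells). The control libraries differed, with 1.21% (29 cells) in library 1 and 9.03% (181 cells) in library 2. Library 2 held 388939 of the 433147 UMIs of control endothelial-like cells, so ratios over control rest mostly on it. For 1 of the models this is the control of the other model. Clusters that mix proximal and distal tubule transcripts held 27.0% of angiotensin II, 43.8% of salt-sensitive and 76.5% of control cells. Macrophage-like cells, led by the complement gene C1qa and by the MHC class II genes H2-Eb1, H2-Aa, H2-Ab1 and Cd74, numbered 4, 3 and 75. Intercalated-like cells, an acid-base regulating type of the collecting duct, numbered 23, 9 and 8. The magnetic selection and the lower depth of the control cells can set these shares. Without the unnamed endothelial clusters 5 and 11 the endothelial-like shares were 35.3%, 30.8% and 2.55%, which turns the order of the hypertension libraries.

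**Figure D1:**
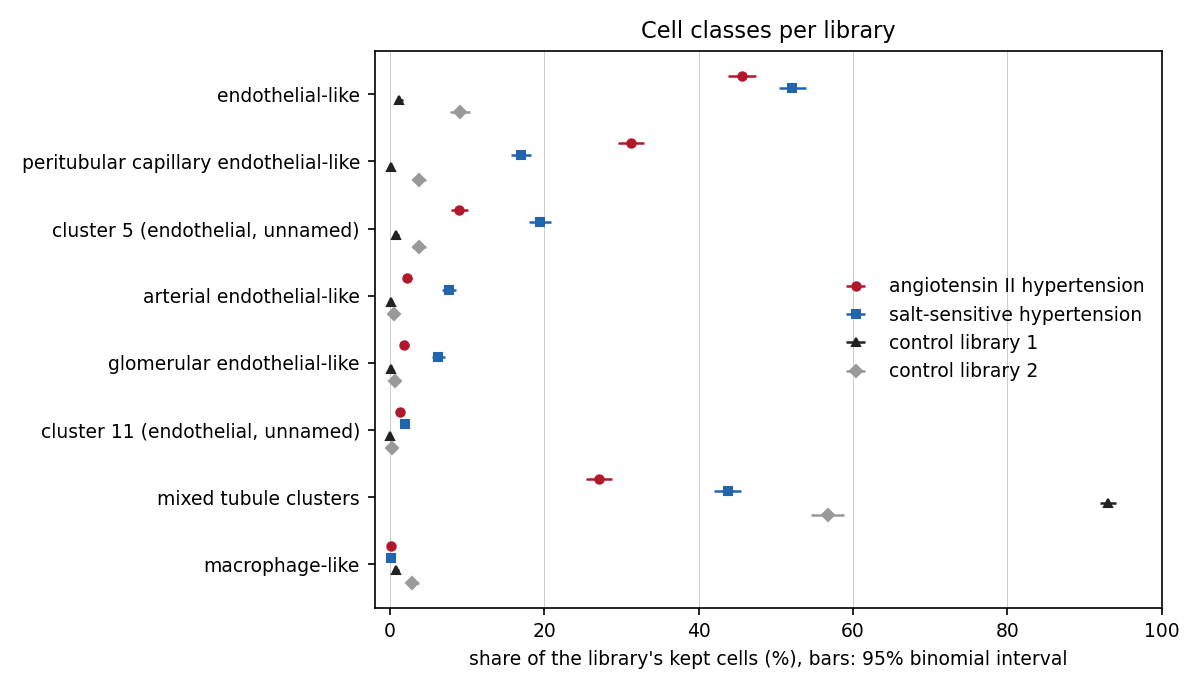
Share of each library's kept cells (%, x axis) in the endothelial classes, the mixed tubule clusters and the macrophage-like cluster, with 95% exact binomial intervals as bars and 1 marker shape per library. Endothelial-like shares of 45.6% and 52.1% in the hypertension libraries lie far above the 1.21% and 9.03% of the control libraries.

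Most endothelial-like cells of the angiotensin II library fell in a peritubular-capillary-like cluster. That cluster held 68.4% of them, against 32.5% of the salt-sensitive and 38.1% of the control endothelial-like cells. It was led by Esm1, Gpihbp1, Npr3 and Igfbp3, and also by the interferon-induced genes Rsad2 and AW112010. Cluster 5, led by the interferon-inducible gene Ifi27l2a and left unnamed, held 19.7%, 37.2% and 43.8%, and was the largest endothelial cluster of the salt-sensitive library and the control. Arterial-like cells were 4.81%, 14.6% and 7.14%, and glomerular-like cells 4.11%, 11.96% and 8.10%. Cluster 11, led by Ptn, Sema3d and Vcam1, held 2.95%, 3.69% and 2.86%. Leading genes such as Igfbp3 differ between libraries within a cluster, so these percentages only show which clusters stand behind each endothelial sum.

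No cluster carried enough lymphatic markers to be called lymphatic-like, and the naming could draw on only 5 of the 10 fixed lymphatic markers. Prox1, the transcription factor that sets lymphatic identity, had a UMI in 11 of 1288 angiotensin II endothelial-like cells (0.854%, 0.427 to 1.52). It had a UMI in 15 of 1706 salt-sensitive cells (0.879%, 0.493 to 1.45) and in 0 of 210 control cells, which allows a share of up to 1.43%. Tubule-bearing barcodes carried it more often at a lower depth, in 2.88%, 3.14% and 2.05% of the mixed tubule cells (median 1150.5, 1066.5 and 813 UMIs, against 4654.5, 2265 and 2257 in the endothelial-like cells). The Prox1 UMIs themselves numbered 11 in the angiotensin II and 41 in the salt-sensitive endothelial-like cells (1.97 against 9.72 CPM), so some salt-sensitive cells held several. Cluster 11 had the highest Prox1 level of all clusters, at 35.8 CPM from 13 UMIs over all libraries. Among the endothelial clusters it was also highest in Sema3d (680 CPM), Nrp2 (314) and Itga9 (162). Cluster 11 was likewise the highest of all clusters in the fixed venous markers Nr2f2 (705 CPM) and Plvap (3463), the latter also a fixed peritubular marker. These levels alone therefore do not set it apart as lymphatic. Its Flt4 level of 74.3 CPM lay below the 139 of the peritubular-capillary-like cluster. Flt4, the VEGF-C receptor of lymphatic and some capillary endothelium, had a UMI in 36.6%, 16.6% and 15.7% of endothelial-like cells and in 3.27%, 2.30% and 1.28% of mixed tubule cells. Both genes were seen together in 7, 3 and 0 endothelial-like cells, where 4.02, 2.497 and 0 would meet by chance. Pdpn, a target of the selection, had a UMI in 42 of 3284 salt-sensitive cells (1.28%) and in 39 of 4414 control cells (0.884%). In the joined hypertension table, where the shared angiotensin II cells hold 88.2% of the UMIs of their own table, 10 of 2881 angiotensin II cells had a Pdpn UMI (0.347%). Reln had a UMI in 13 of those 2881 cells (0.451%), in 22 of 3273 salt-sensitive cells of that table (0.672%) and in 49 of 4414 control cells (1.11%). Lyve1, Mmrn1 and Ccl21a are not analysed here.

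Lymphatic markers were compared across all endothelial-like cells instead. Flt4 stood at 126 CPM (UMIs scaled to equal library totals) in the angiotensin II library, 78.0 in the salt-sensitive library and 85.4 in the control. Its log2 ratio was 0.53 (95% interval 0.08 to 1.08) for angiotensin II over control, −0.12 (−0.62 to 0.40) for salt-sensitive over control and 0.66 (0.50 to 0.88) for angiotensin II over salt-sensitive. Within the peritubular-capillary-like cluster the last ratio was 0.15. With each cell thinned to 1000 UMIs the Flt4 ratios over control were 1.97 and 1.59. Only 148 control cells remained there, so few control Flt4 UMIs stand behind these ratios, and no interval is given for them. Itga9, a lymphatic valve integrin, gave −0.10, 0.37 and −0.47 (−0.71 to −0.30) in the same order. Nrp2, a co-receptor for VEGF-C, gave 0.35, −0.03 and 0.38, and the last turned to −0.24 within the peritubular-capillary-like cluster. Sema3d gave 0.02, −0.21 and 0.23, and the last turned to −0.07 with the endothelial clusters weighted equally. Its ratio for angiotensin II over control was 1.01 (0.05 to 2.44, 7 control UMIs) in peritubular-capillary-like cells. Without clusters 5 and 11, the latter with this gene among its leading genes, Sema3d gave 1.23 over control and 1.15 between the models. Pecam1 itself differed little between the hypertension libraries (1034 and 1065 CPM), and its ratios over control were 0.43 and 0.48. The fixed list of lymphangiogenesis and lymphatic identity genes had a median log2 ratio of 0.22 (0.09 to 0.33, 15 of 23 genes higher) for angiotensin II and 0.00 (−0.06 to 0.16, 13 of 25) for salt-sensitive over control. Between the models its median was 0.17 (0.07 to 0.21, 14 of 25 genes higher in angiotensin II), which turned to −0.04 with the endothelial clusters weighted equally. In cells with a UMI of Prox1 or Flt4, both members of the list, its medians over control were 0.91 and 0.81. Only 21.9% of those control cells were endothelial-like.

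The comparison of angiotensin II hypertension with control asks what this model does to the endothelium of the kidney. Endothelial-like cells of the angiotensin II library carried more interferon-response and antigen-presentation transcripts. Of 28 interferon-response genes 27 were higher, with a median log2 ratio of 0.53 (0.45 to 0.65), above all 10000 random lists of matched expression. The MHC class II presentation list had a median of 0.54 (0.33 to 0.98) with 5 of 7 genes higher. Among them were Cd74, the invariant chain that guides class II molecules (chromosome 18, 60803848 to 60812652 in GRCm38), at 441 against 201 CPM (1.12, 0.83 to 1.46), and H2-DMa, which helps load peptide (1.07, 0.18 to 2.79). The MHC class I list had a smaller median of 0.31 (0.22 to 0.40) with 16 of 17 genes higher.

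Within the peritubular-capillary-like cluster alone these medians were smaller. The interferon median was 0.22 (0.13 to 0.35, 23 of 28 genes higher), MHC class II 0.33 (0.11 to 0.86, 6 of 7) and MHC class I 0.02 (−0.05 to 0.15, 11 of 17). Cd74 kept a ratio of 1.18 (0.81 to 1.62) there. In cluster 5 all 28 interferon genes were higher in the angiotensin II library, with a median of 1.02, beside tubule markers of 714 against 5482 CPM and a median depth of 3864.5 against 879 UMIs in control. The mixed tubule clusters 0, 1 and 3 moved alike: their interferon medians were 0.91, 0.95 and 0.95 and their MHC class II medians 1.21, 0.96 and 0.58. Macrophage genes summed to 32.9 CPM in angiotensin II and 60.03 in control endothelial-like cells, but to 224 and 152 CPM in the mixed tubule clusters. When the 5 endothelial clusters were weighted equally, the MHC class II median turned to −0.27 and Cd74 to −0.03. That setting gives 3 of 5 parts of the control to clusters 11, 9 and 12 with 6, 15 and 17 control cells. In the 15 arterial-like ones macrophage genes reached 167 CPM, against 12.6 in angiotensin II. As a mean over cells Cd74 gave 0.39.

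Leukocyte adhesion genes were also higher in the angiotensin II endothelium, as were some single genes of other functions. Leukocyte adhesion molecules had a median of 0.35 (0.14 to 0.59, 8 of 10 higher) and, within the peritubular-capillary-like cluster, 0.50 (0.23 to 0.95, 6 of 9). There Vcam1, the ligand of a leukocyte integrin, reached 60.01 CPM against 9.20, a log2 ratio of 2.19 (0.84 to 5.76) resting on 2 control UMIs (1.05 at clustering resolution 0.5). Single genes higher over all endothelial-like cells were the matricellular gene Sparcl1 (500.3 against 164 CPM, 1.58), the junctional adhesion gene Nectin2 (1.59, 0.87 to 2.94), the RANK receptor gene Tnfrsf11a (1.43) and the cholesterol exporter gene Abca1 (1.31). The transcription factor gene Sox4 was higher by 1.11 and the stress sensor gene Keap1 by 1.11. Nos3, which encodes endothelial nitric oxide synthase, was higher by 1.11 (0.16 to 2.55) in the peritubular-capillary-like cluster, and Edn1, the endothelin-1 gene, was lower (−1.36, −2.22 to −0.70). With clusters weighted equally the Sox4 ratio was 0.27.

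Cyp26b1 had the lowest named ratio within the peritubular-capillary-like cluster. This gene encodes a cytochrome P450 that degrades retinoic acid (chromosome 6, 84571414 to 84593908). It stood at 56.0 CPM in angiotensin II against 392 in control endothelial-like cells (−2.70, −3.08 to −2.53), and at 62.7 against 465 CPM in the peritubular-capillary-like cluster (−2.79, −3.23 to −2.54). Ezh2, the histone methyltransferase of Polycomb repressive complex 2, stood at 107 against 254 CPM (−1.20, −1.54 to −0.93) and gave −1.23 (−1.66 to −0.85) in that cluster. Control library 2 held 168 of the control's 170 Cyp26b1 UMIs and 105 of its 110 Ezh2 UMIs. Lpl, lipoprotein lipase (−2.48), and Pi16 (−1.39), which leads the glomerular-like cluster, gave −0.56 and −0.20 among peritubular-capillary-like cells.

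Respiratory-chain transcripts were lower in the angiotensin II endothelium. Of 28 nuclear-encoded oxidative phosphorylation genes 27 were lower, with a median of −0.52 (−0.60 to −0.45), below all 10000 random lists. The list member Atp5g1, a subunit of ATP synthase, gave −1.16. Outside this list the lactate dehydrogenase gene Ldhb (−1.70) and the peroxidase gene Prdx5 (−1.55) were lower. Tubule markers moved the same way, at 835 CPM in angiotensin II and 2599.6 in control endothelial-like cells, and the tubule genes Wfdc15b (−5.24), Ppp1r1a (−4.26) and Spp1 (−3.66) gave the lowest ratios. Peritubular-capillary-like cells alone gave a median of −0.25 (−0.34 to −0.14, 24 of 28 lower), with Atp5g1 at −0.27, Ldhb at −0.53 and Prdx5 at −0.36. Tubule markers in that cluster stood at 807 CPM in angiotensin II against 1196 in control cells. Without control library 1, which gave 29 endothelial-like cells, the median over all clusters was −0.29, Atp5g1 −0.50, Ldhb −0.88, Prdx5 −0.56, Wfdc15b −2.80, Ppp1r1a −1.58 and Spp1 −2.42. In cells with a UMI of Prox1 or Flt4, of which 21.9% were endothelial-like in the control and 87.8% in the angiotensin II library, the list's median turned to 0.43.

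The remaining lists moved less over control. The shared genes hold only 5 of 25 chemokine and 18 of 32 NF-kB and acute inflammation list genes. Ccl2, Ccl5, Cxcl10, Tnf, Il1b and Il6 are among those left out. Endothelial junction genes had a median of 0.21 (0.09 to 0.36, 11 of 13 higher) and vasoactive mediators 0.19 (0.08 to 0.35, 12 of 16). NF-kB and acute inflammation genes gave 0.14 (0.01 to 0.39, 14 of 18), extracellular matrix and TGF-beta genes 0.15 (0.03 to 0.32, 16 of 28), and apoptosis and p53 genes 0.20 (−0.04 to 0.40, 8 of 14). Chemokines gave 0.23 (−0.11 to 0.55, 4 of 5), hypoxia and glycolysis genes 0.11 (−0.10 to 0.17), dissociation and immediate early genes 0.09 (−0.04 to 0.24), mineralocorticoid, glucocorticoid and sodium handling genes −0.03 (−0.23 to 0.20), and oxidative stress genes −0.07 (−0.23 to 0.03). Fatty acid uptake and oxidation genes had a median of −0.31 (−0.47 to −0.05, 14 of 20 lower) and complement and coagulation genes −0.28 (−0.38 to 0.16, 5 of 9 lower). In peritubular-capillary-like cells the fatty acid median was 0.00 and the complement median turned to 0.39.

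**Figure D2:**
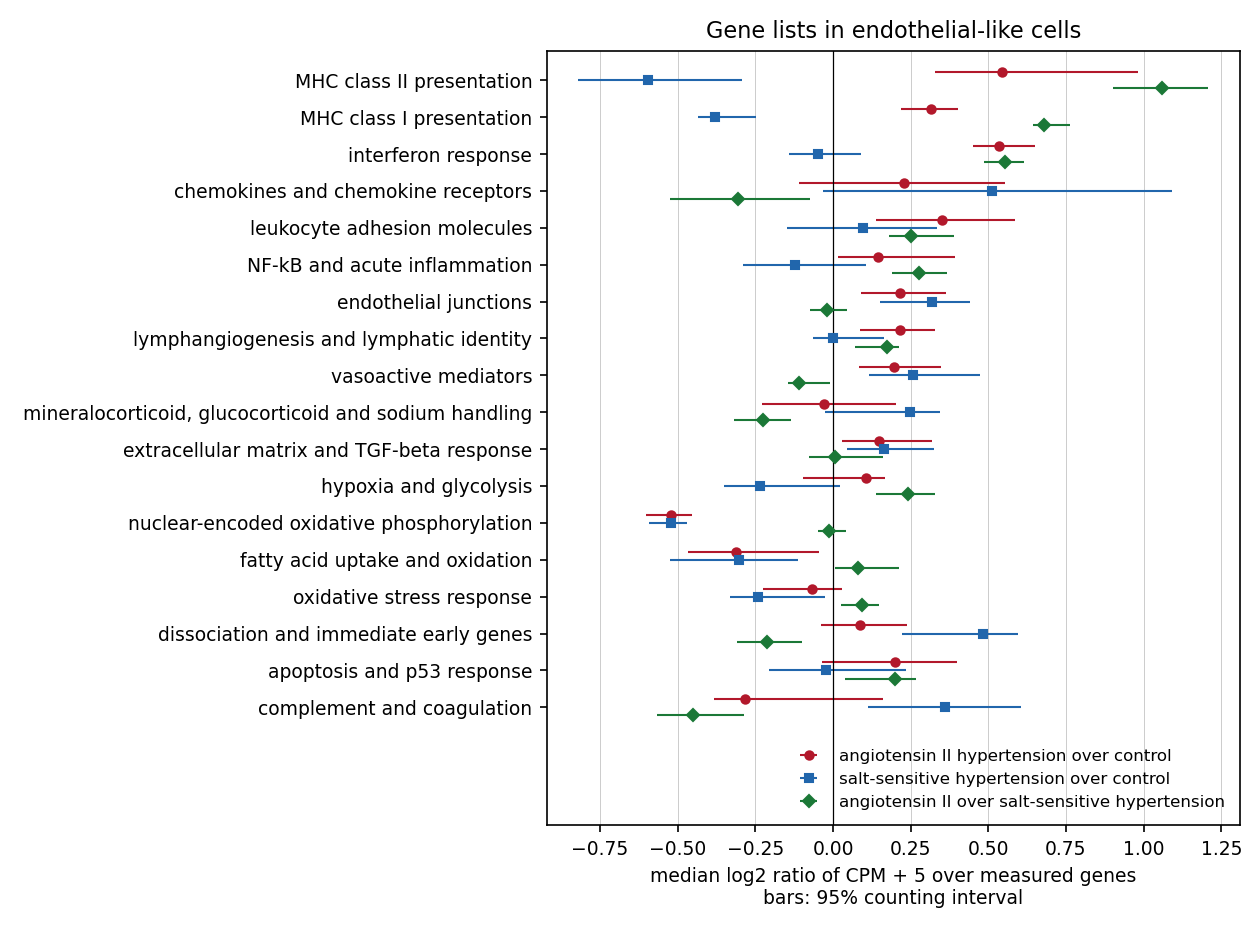
Median log2 ratio of CPM + 5 (x axis) over the measured genes of each of the 18 fixed lists in endothelial-like cells, with 95% counting intervals as bars and 1 marker shape per comparison. MHC class II genes lie at 0.54 for angiotensin II over control, −0.59 for salt-sensitive over control and 1.06 between the models, and oxidative phosphorylation genes at −0.52 in both comparisons with control.

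The comparison of salt-sensitive hypertension with control asks the same question of the other model. Here most dissociation and immediate early genes were higher and most antigen-presentation genes lower in the endothelium. Dissociation and immediate early genes, which include the heat-shock genes that tissue digestion can induce, had a median of 0.48 (0.22 to 0.59, 16 of 23 higher), above all 10000 random lists. Hsp90aa1, the inducible HSP90 chaperone gene (chromosome 12, 110690605 to 110702728), stood at 408 against 187 CPM (1.11, 0.80 to 1.47). In the peritubular-capillary-like cluster it stood at 379 against 124 CPM (1.57, 1.05 to 2.22), where the list's median was 0.46 (−0.03 to 0.58, 12 of 21). Hspa1b gave 1.08 (0.62 to 1.70), and its near-identical copy Hspa1a could share reads with it. The collagen hydroxylase gene P4ha1 (1.11) was higher too.

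Summed over all endothelial-like cells, antigen presentation moved opposite to the angiotensin II model. The MHC class II median was −0.59 (−0.82 to −0.29), with 6 of 7 genes lower, among them H2-Eb1 (−1.09, −1.62 to −0.69) and the class II transactivator gene Ciita (−1.09, −2.66 to −0.29, 30 against 9 UMIs). The MHC class I median was −0.38 (−0.44 to −0.25) with 16 of 17 genes lower. In peritubular-capillary-like cells the class II median was −0.22 (−0.44 to 0.13, 5 of 6 lower) and the class I median −0.33 (−0.48 to −0.20, 14 of 17 lower). The mixed tubule clusters 0, 1 and 3 moved the other way, with class II medians of 0.79, 0.74 and 0.37. Macrophage genes summed to 23.9 CPM in salt-sensitive and 60.03 in control endothelial-like cells, but to 175 and 152 CPM in the mixed tubule clusters. With the endothelial clusters weighted equally the class II median was −0.29, beside −0.27 for angiotensin II, on the same few control cells. Macrophage genes in arterial-like cells stood at 8.66 CPM in salt-sensitive and 167 in control. Thinning each cell to 1000 UMIs gave −0.18, and −0.43 for H2-Eb1. In cells with a UMI of Prox1 or Flt4 the class II median turned to 0.58 and the class I median to 0.61, but only 21.9% of those control cells were endothelial-like, against 79.6% of the salt-sensitive ones.

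Interferon-response genes gave no common direction over all endothelial-like cells, with a median of −0.05 (−0.14 to 0.09) and 13 of 28 higher. The clusters differed: the median was −0.08 (−0.17 to 0.08) in the peritubular-capillary-like cluster and 0.66 with 26 of 28 higher in cluster 5. Cluster 5 held 92 control cells, in which tubule markers summed to 5482 CPM against 1575 in the salt-sensitive cells. Ifi27l2a, which leads cluster 5, gave 1.56 over all endothelial-like cells. With each cell thinned to 1000 UMIs the interferon median was 0.19, as a mean over cells 0.17, and without clusters 5 and 11 −0.41.

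Inflammatory and vascular genes of the salt-sensitive peritubular-capillary-like cells moved both ways. Lower were Il33, an alarmin cytokine gene (−1.36, −2.13 to −0.74), Relb, a subunit of the non-canonical NF-kB pathway (−1.39, −2.76 to −0.45), Nostrin, which binds endothelial nitric oxide synthase (−1.03), and Crlf2, a receptor subunit for thymic stromal lymphopoietin (−1.55). Higher was Vcam1, which stood at 42.4 against 9.20 CPM (1.74, 0.28 to 5.29, 2 control UMIs, and 0.51 at clustering resolution 0.5). Adhesion molecules had a median of 0.41 (0.02 to 0.90, 7 of 9 higher) there, which turned to −0.20 with cells thinned to 1000 UMIs, and 0.10 (−0.15 to 0.34, 6 of 10) over all endothelial-like cells. Vegfc (2.22), Cxcl12 (2.07), Eln (1.76), Tgfb2 (1.72) and Ptn (1.999) were among the highest over all endothelial-like cells, but they lead the arterial-like cluster or, for Ptn, cluster 11. Tgfb2 gave 0.01 within the peritubular-capillary-like cluster.

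Respiratory-chain transcripts were lower over control, as in the angiotensin II model. Both models' ratios divide by the same 210 control cells, so the likeness is no independent repeat. All 28 oxidative phosphorylation genes were lower, with a median of −0.52 (−0.59 to −0.47). The list member Atp5g1 gave −1.04. Outside this list Uqcrfs1, the Rieske protein of complex III (−1.54), the malate dehydrogenase gene Mdh1 (−1.43), Ldhb (−1.70) and Prdx5 (−1.68) were lower. Tubule markers summed to 1604 CPM against 2599.6 in control, and Wfdc15b (−4.48), Ppp1r1a (−3.53) and Spp1 (−2.98) again gave the lowest ratios. In peritubular-capillary-like cells the list's median was −0.20 (−0.30 to −0.11, 26 of 28 lower), Mdh1 gave −0.24, Ldhb −0.68, Prdx5 −0.41 and Atp5g1 −0.02, and Ppp1r1a turned to 0.41. Tubule markers were higher in that cluster, at 1741 CPM in salt-sensitive against 1196 in control cells. Without control library 1 the median was −0.29, Uqcrfs1 −1.001, Mdh1 −0.72, Ldhb −0.88, Prdx5 −0.68, Atp5g1 −0.39, Wfdc15b −2.05, Ppp1r1a −0.84 and Spp1 −1.73. Without clusters 5 and 11 Wfdc15b turned to 0.68 and Ppp1r1a gave −0.22. In cells with a UMI of Prox1 or Flt4, few of them endothelial-like in the control, the list's median turned to 0.42 and Wfdc15b to 0.48.

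Among the other lists, endothelial junction genes had a median of 0.32 (0.15 to 0.44, 9 of 13 higher) over control. Complement and coagulation genes gave 0.36 (0.11 to 0.61, 7 of 10) and vasoactive mediators 0.26 (0.12 to 0.47, 13 of 17), the latter turning to −0.14 within the peritubular-capillary-like cluster. Mineralocorticoid, glucocorticoid and sodium handling genes gave 0.25 (−0.03 to 0.34), extracellular matrix and TGF-beta genes 0.16 (0.04 to 0.33), and chemokines 0.51 (−0.03 to 1.09, 3 of 5), which turned to −0.42 in peritubular-capillary-like cells. Hypoxia and glycolysis genes gave −0.24 (−0.35 to 0.02), oxidative stress genes −0.24 (−0.33 to −0.03), fatty acid genes −0.30 (−0.52 to −0.11), NF-kB genes −0.12 (−0.29 to 0.11) and apoptosis genes −0.02 (−0.21 to 0.23).

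**Figure D3:**
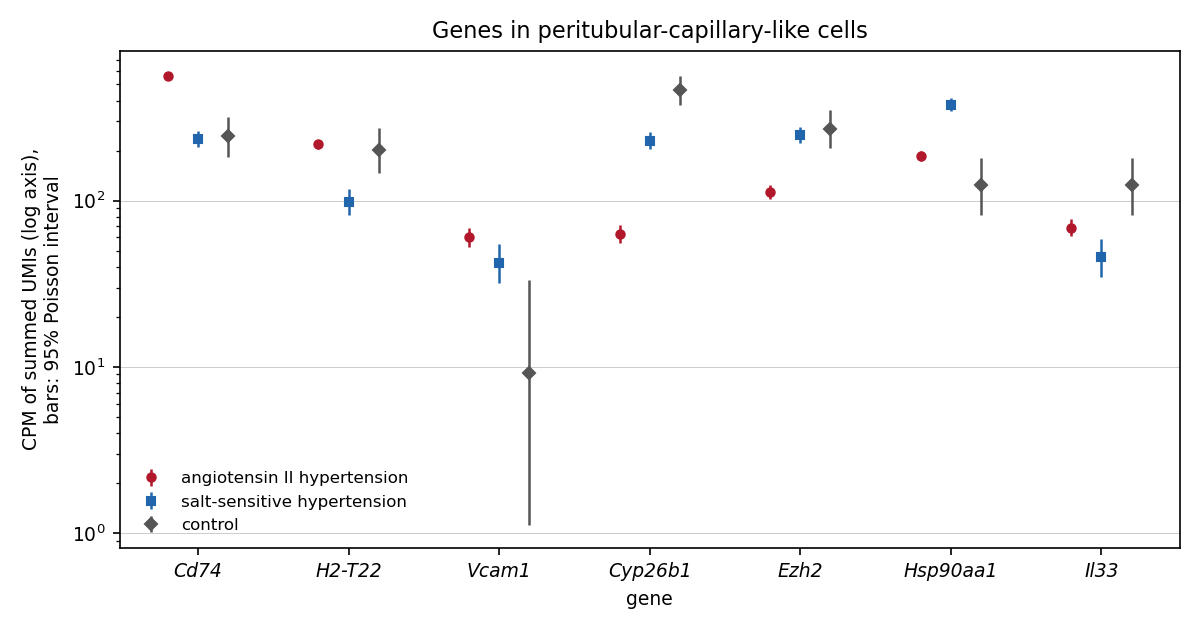
CPM of summed UMIs (log axis) of 7 genes in peritubular-capillary-like cells of each hypertension library and the summed control, with 95% exact Poisson intervals as bars. Cyp26b1 stands at 62.7 CPM in angiotensin II, 230 in salt-sensitive and 465 in control cells, and Hsp90aa1 at 186, 379 and 124 CPM.

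The hypertension libraries were compared directly to ask what differs between the models, with no control shared. Summed over these cells, MHC class II transcripts differed: all 7 measured genes were higher in the angiotensin II endothelium, with a median log2 ratio of 1.06 (0.90 to 1.21). Cd74 stood at 441 against 149 CPM (1.53, 1.44 to 1.69). The class II chains H2-Aa (1.48, 1.34 to 1.82), H2-Ab1 (1.17, 1.05 to 1.37) and H2-Eb1 (1.06, 0.91 to 1.36) were higher as well. All 17 MHC class I genes were higher, with a median of 0.68 (0.64 to 0.76), including H2-Q7 (1.05) and H2-T22 (1.19), which belong to gene families with shared sequence whose reads could be split between members. Of 28 interferon-response genes 26 were higher, with a median of 0.55 (0.49 to 0.62), and Ifit3, an interferon-induced antiviral gene, gave 1.002 (0.89 to 1.18). These 3 medians lay above all 10000 random lists.

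In peritubular-capillary-like cells the MHC class II median was 0.70 (0.50 to 0.88, 7 of 7), MHC class I 0.41 (0.35 to 0.51, 15 of 17) and interferon 0.31 (0.24 to 0.35, 25 of 28). The weights of the clusters matter: with endothelial clusters weighted equally the class II median was 0.22, Cd74 0.22 and the interferon median 0.35. Mixed tubule clusters 0, 1 and 3 gave interferon medians of 0.43, 0.28 and 0.58 and class II medians of 0.43, 0.07 and 0.31. Over these tubule clusters macrophage genes summed to 224 CPM in angiotensin II and 175 in salt-sensitive cells. Tubule markers summed to 835 and 1604 CPM in the angiotensin II and salt-sensitive endothelial-like cells.

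Single genes of other functions also differed between the models when summed over all endothelial-like cells. The peritubular-capillary-like cluster held 68.4% of these cells in the angiotensin II and 32.5% in the salt-sensitive library. Such differences may follow the cluster makeup, and values within that cluster are not given here for Ednrb, Ramp3 and Tbxa2r. Ednrb, the endothelin B receptor gene (438 against 195 CPM, 1.14), Ramp3, a part of adrenomedullin receptors (421 against 171 CPM, 1.28), and Tbxa2r, the thromboxane receptor gene (262 against 114 CPM, 1.17), were higher in angiotensin II. Enpep, the aminopeptidase that shortens angiotensin II, gave 1.25, and 0.43 within the peritubular-capillary-like cluster. Igfbp3 (1.46) and Gpihbp1 (1.10) define that cluster. Ptn (−3.02), Tgfb2 (−2.11), Pi16 (−1.98) and Cxcl12 (−1.80) were among the lowest, and they lead cluster 11, the arterial-like or the glomerular-like cluster. The whole list of vasoactive mediators had a median of −0.11 (−0.14 to −0.01, 11 of 17 lower), which turned to 0.33 (0.15 to 0.44, 10 of 15 higher) within the peritubular-capillary-like cluster.

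Among peritubular-capillary-like cells Cyp26b1 was lower in the angiotensin II than in the salt-sensitive model. It stood at 62.7 CPM in angiotensin II against 230 in salt-sensitive cells (−1.79, −2.12 to −1.63), and Ezh2 gave −1.11 (−1.35 to −0.93). Hsp90aa1 (−1.01), its co-chaperone gene Hsph1 (−1.16), the small heat-shock gene Hspb1 (−0.88) and P4ha1 (−1.003) were lower in angiotensin II, while the dissociation list as a whole had a median of −0.04 (−0.14 to 0.09). The tetraspanin gene Cd151 (1.22), the connexin gene Gja4 (1.18), Crlf2 (1.18), Cd74 (1.23) and H2-T22 (1.10) were higher. NF-kB and acute inflammation genes had a median of 0.22 (0.12 to 0.39, 16 of 18) and adhesion molecules 0.31 (0.16 to 0.36, 7 of 10). With cells thinned to 1000 UMIs P4ha1 gave −0.26, Gja4 gave 0.55 at clustering resolution 0.5, and Cd74 gave 0.69 with a minimum of 500 genes per cell.

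Arterial-like and glomerular-like cells were compared between the hypertension libraries only. Some smooth muscle and matrix genes were higher in the 62 arterial-like cells of the angiotensin II library than in the 249 of the salt-sensitive library. Tagln (2.66, 2.12 to 3.64) and Acta2 (2.63) encode smooth muscle proteins, are fixed markers of mural cells and are among the leading genes of cluster 7, where fibroblast and mural markers tie. Ccn2 (2.16) is a TGF-beta target, Bmp4 (2.03) a growth factor gene and Fn1 (1.30) encodes fibronectin. Their extracellular matrix and TGF-beta list had a median of 0.20 (0.08 to 0.53, 16 of 23 higher). At clustering resolution 2 Ccn2 gave 0.93 and Hspa1a −0.78, and with a minimum of 500 genes per cell Tagln gave 1.89. Cyp26b1 had 0 UMIs in the angiotensin II arterial-like cells and 63 in the salt-sensitive ones, whose interval of the log2 ratio ends at −2.28; with doublets kept the ratio was −1.94. MHC class I genes had a median of 0.24 (0.12 to 0.47, 12 of 17) with H2-Q7 at 1.34, interferon genes 0.06 (−0.07 to 0.23, 17 of 28), and dissociation genes −0.30 (−0.56 to −0.11, 16 of 22 lower), with Hspa1a at −1.44 and Hspb1 at −1.17.

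In glomerular-like cells, 53 against 204, interferon genes had a median of 0.70 (0.44 to 0.83, 20 of 21 higher) and MHC class I genes 0.60 (0.40 to 0.74, 15 of 16), with H2-Q6 at 2.02 and H2-Q7 at 1.56. Edn1 was higher by 1.82 (1.16 to 2.71) and Acta2 by 2.32 (1.54 to 3.64). The flow-responsive transcription factor gene Klf4 was lower (−1.74, −2.53 to −1.12), as were Hspa1a (−2.56, −4.22 to −1.58) and Hspa1b (−2.06, −3.56 to −1.11), which rest on 6 and 7 UMIs in the angiotensin II cells. Dissociation genes had a median of −0.48 (−0.75 to −0.25, 15 of 20 lower), which was −1.24 with cells thinned to 1000 UMIs.

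The other lists between the models, over all endothelial-like cells, gave the following medians. Higher in angiotensin II were adhesion molecules (0.25, 0.18 to 0.39, 8 of 10), NF-kB genes (0.28, 0.19 to 0.37, 14 of 18), hypoxia and glycolysis genes (0.24, 0.14 to 0.33, 16 of 22), apoptosis genes (0.20, 0.04 to 0.27), oxidative stress genes (0.09, 0.03 to 0.15) and fatty acid genes (0.08, 0.01 to 0.21). Lower were complement and coagulation genes (−0.45, −0.57 to −0.29, 9 of 10 lower), mineralocorticoid, glucocorticoid and sodium handling genes (−0.22, −0.32 to −0.14) and dissociation genes (−0.21, −0.31 to −0.10), with Hspa1b at −1.20. Chemokines gave −0.31 (−0.53 to −0.07, 3 of 5 lower), which turned to 0.25 within the peritubular-capillary-like cluster, where the complement median was 0.00. Junction genes (−0.02), extracellular matrix genes (0.01) and oxidative phosphorylation genes (−0.01) lay near 0.

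The models' ratios over the common control were also set against each other across genes, which are not independent replicates. Over 8724 genes in endothelial-like cells Pearson's r was 0.675 and 74.7% of genes had the same sign. Unchanged groups simulated against the same control gave r of 0.923 and 87.1%. The covariance was 0.149 against 0.0982 simulated, a difference of 0.0507. Over 5536 genes in peritubular-capillary-like cells r was 0.748 (simulated 0.910), the same-sign share 77.1% (85.9%) and the covariance 0.158 (0.123), a difference of 0.0349. The simulation draws counting error only, so part of the excess covariance may come from the shared control.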

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

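Of the tests weighed here, those within the peritubular-capillary-like cluster, with endothelial clusters weighted equally and with tubule RNA subtracted were chosen only after the results they bear on were seen. The results listed stand out because their values over all endothelial-like cells point in opposite directions over control in the models. The differences between the ratios were not tested, since each group is 1 library. Control library 2, the control of only 1 of the models, gave 388939 of the 433147 control UMIs behind both ratios.

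MHC class II presentation genes had a median log2 ratio of 0.54 in angiotensin II and −0.59 in salt-sensitive endothelial-like cells. MHC class I genes had 0.31 and −0.38, and Cd74 1.12 and −0.42. The opposition depends on the setting: with endothelial clusters weighted equally MHC class II had −0.27 and −0.29 and Cd74 for angiotensin II −0.03, where 3 of the 5 clusters hold only 6, 15 and 17 control cells and the 15 carry macrophage genes at 167 CPM, and in cells with a UMI of Prox1 or Flt4 MHC class II had 1.28 and 0.58, where 21.9% of the control cells were endothelial-like. Pi16, which leads the glomerular-like cluster, had −1.39 and 0.59, and Ptn, which leads cluster 11, −1.02 and 1.999.

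The higher MHC class II transcripts of the angiotensin II over the salt-sensitive endothelium (median 1.06) were weighed. Macrophage RNA or doublets stay open. The median of 6 macrophage genes was 0.13 (−0.03 to 0.29), but their sums were only 32.9 and 23.9 CPM. The pseudocount understates the change of such low genes, so this median could not speak against macrophage RNA. Within the peritubular-capillary-like cluster their sum was lower in angiotensin II (36.6 CPM) than in salt-sensitive cells (47.0 CPM). Dendritic and B cells, none of whose markers are among the genes used, were not covered. Greater depth stays open. Cells thinned to 1000 UMIs gave 0.91 (0.76 to 1.25 in a second draw), but thinning leaves each cell's expected CPM unchanged. Cells also kept the clusters found at full depth, so this value could not speak against depth. Tubule RNA diluting the salt-sensitive cells is argued against by a median of 1.08 with that RNA subtracted. Different shares of endothelial subtypes stay open and may account for part of the difference. The MHC class II median was 0.70 (0.48 to 0.89) within the peritubular-capillary-like cluster, 66.2% of the whole. Clusters were found from the same expression, without integration of libraries. Interferon-induced genes are among the leading genes of that cluster and of the largest unnamed endothelial cluster. A smaller median within a cluster can thus follow partly from sorting cells on related genes, and does not measure the part due to subtypes. The median was −0.26 in arterial-like cells from 15 and 61 UMIs and 0.68 in glomerular-like cells from 15 and 21 UMIs. The peritubular-capillary-like cluster held 5159 of 5707 MHC class II UMIs in angiotensin II, but 854 of 1696 in salt-sensitive cells. The unnamed endothelial clusters were left out of this check. The largest of them held 254 angiotensin II and 635 salt-sensitive cells, so whether the difference holds there is not shown. A difference between the hypertension models is the open biological hypothesis, which single libraries do not separate from a difference between preparations.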

How the results depend on the processing

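Chosen only after results were seen were the tests on the peritubular-capillary-like cluster alone, with clusters weighted equally, with clusters of 3 top-50 endothelial markers only, with tubule RNA subtracted, with the joined table and with the guard against every cluster. Of 1855 values of single genes 1623 stayed within their counting interval, 220 left it and 12 turned direction from an interval clear of 0 (2 of them Flt4 in cells chosen by it); of 1257 values of other lists 1135, 107 and 15. The lists of MHC class II and interferon genes stayed within their interval in 85 of 112 values and reversed in 2. The interferon median over control stayed positive for angiotensin II under 19 of 19 alternatives, and MHC class II and interferon between the models under 18 of 18. MHC class II over control kept its sign under 18 of 19 in each model, and interferon for salt-sensitive over control under 15 of 19. No filter on cells, centring on the median gene, leaving out tubule and ribosomal genes, and members with 100 UMIs moved nothing. They could move little, since the cell filter had removed 0 cells. The median gene already lay at 0.003, 0.013 and −0.031 in endothelial-like cells, and a UMI minimum leaves a single gene's ratio as it is. All these values count as staying. Of single-gene values, 21 stayed, 37 left and 2 turned in the peritubular-capillary-like cluster alone. These counts were 28, 34 and 6 in cells with a UMI of Prox1 or Flt4. With clusters weighted equally they were 42, 25 and 3. Control library 1 alone gave no value from 29 endothelial-like cells, the mitochondrial limits could not act, and Mmrn1 is not used here. Thinning left out 80 angiotensin II, 143 salt-sensitive and 62 control endothelial-like cells, and control depth limits every ratio over control. No paired analysis was possible because each group has 1 library and no result comes from a test.

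In what follows A2 over control, SS over control and A2 over SS stand for the ratios of the angiotensin II and salt-sensitive libraries, and causes were not tested except where the setting's construction shows them. With at least 500 genes per cell, endothelial-like shares were 51.3% (angiotensin II), 55.2% (salt-sensitive) and 5.65% (control), since shallower tubule barcodes leave the total. With clusters of 3 top-50 markers only they were 35.3%, 30.8% and 2.55%, since clusters 5 and 11 leave the class; MHC class II A2 over SS was then 1.36, interferon 0.38, −0.41 and 0.66 (A2 over control, SS over control, A2 over SS), chemokines A2 over SS 0.27 and Wfdc15b SS over control 0.68. In cells with a UMI of Prox1 or Flt4, of which 21.9% were endothelial-like in the control, MHC class II was 1.28, 0.58 and 0.79, interferon 1.56, 0.86 and 0.62, oxidative phosphorylation over control 0.43 and 0.42, MHC class I SS over control 0.61, vasoactive mediators A2 over SS 0.0586, Atp5g1 over control 0.0877 and 0.0311, Flt4, on which these cells are chosen, A2 over control −0.20 and A2 over SS −0.23, H2-Eb1 SS over control 0.70 and Wfdc15b 0.48. With each cell thinned to 1000 UMIs, MHC class II SS over control was −0.18, interferon SS over control 0.19 and A2 over SS 0.46, chemokines A2 over SS 0.24, vasoactive mediators A2 over SS 0.0496 and adhesion SS over control in peritubular-capillary-like cells −0.20. With endothelial clusters weighted equally, 3 of them with 6, 15 and 17 control cells, MHC class II was −0.27, −0.29 and 0.22, interferon A2 over control 0.30 and A2 over SS 0.35, Cd74 A2 over control −0.0267, and A2 over SS Nrp2 −0.27, Sema3d −0.0665, chemokines 0.24 and lymphangiogenesis −0.0365. As a mean over cells, A2 over SS was 0.85 for MHC class II and 0.44 for interferon, and interferon SS over control 0.17. In the peritubular-capillary-like cluster alone, MHC class II SS over control was −0.22 and A2 over SS 0.70, interferon A2 over control 0.22 and A2 over SS 0.31, vasoactive mediators SS over control −0.14 and A2 over SS 0.33, and A2 over SS chemokines 0.25, complement 0.00307 and Nrp2 −0.24; Ppp1r1a SS over control was 0.41 and fatty acid genes A2 over control 0.00187. With a pseudocount of 20 CPM MHC class II A2 over SS was 0.89, and with tubule free RNA subtracted interferon A2 over control was 0.45.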

Other observations

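Here the test of a shared batch was chosen only after the result was seen, as were the tubule genes named. Tubule transcripts differed between the libraries as well. In the mixed tubule clusters the angiotensin II library was low in Slco1a1, a proximal tubule organic anion transporter gene, at 20.2 CPM against 99.2 in salt-sensitive and 146 and 163 in control libraries 1 and 2. Pde10a, a cyclic nucleotide phosphodiesterase gene, was high there at 362 CPM against 134, 72.1 and 91.1. Kynu, a kynurenine pathway enzyme gene, stood at 69.6 CPM against 22.5, 15.1 and 6.33, and Hao2, a peroxisomal hydroxy acid oxidase gene, at 141 against 43.0, 61.2 and 77.2. The same direction held in clusters 0, 1 and 3 for Slco1a1, with log2 ratios over control of −2.58, −2.60 and −2.85, and for Pde10a with 2.16, 1.93 and 2.44.

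Oxidative phosphorylation genes, lower over control in the endothelium, were not lower as a list in the mixed tubule clusters 0, 1 and 3: their medians over control were 0.46, 0.41 and 0.26 for angiotensin II and 0.27, 0.30 and 0.02 for salt-sensitive hypertension. In cluster 5 they were lower, with −1.08 and −1.12, beside tubule markers of 714, 1575 and 5482 CPM in angiotensin II, salt-sensitive and control cells. The MHC class I medians of the mixed tubule clusters over control were 0.88, 1.002 and 1.10 for angiotensin II and 0.42, 0.71 and 0.19 for salt-sensitive hypertension. These depend on the control library: over the mixed clusters H2-D1 stood at 31.8 CPM in control library 1 and 91.1 in library 2, against 228 in angiotensin II and 98.2 in salt-sensitive cells, and in cluster 1 the salt-sensitive 109 CPM lay below the 114 of control library 2.

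The nature of the mixed tubule barcodes was weighed, since proximal and distal markers share most of them. The split of marker UMIs between proximal and distal genes had a dispersion between barcodes of 3.43 (2.98 to 3.88) in the angiotensin II library. It was 1.95 (1.74 to 2.19) in the salt-sensitive library and 2.17 (1.91 to 2.47) in control library 2. Simulated barcodes of 1 source gave at most 1.10. This argues against free RNA of 1 composition as the only source in those libraries. Control library 1, with 2224 mixed barcodes, gave 1.35, under the limit set for this test, so free RNA stays open there. A mixture of free RNA and cells was not tested. Doublets of tubule cells stay open, because the dispersions, lowest at 1.35 (1.27 to 1.43) in control library 1, lie below the 14.9 of simulated pairs of pure cells but not all near that of 1 source. The simulated pairs did not take the marker counts or proximal shares of these barcodes (74.3% to 81.9% proximal). The 14.9 is thus not the value that doublets would give here. No biological explanation was tested.

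Tubule transcripts also split the libraries across the groups: Trim30a, an interferon-inducible gene, stood at 49.5 CPM in angiotensin II and 68.3 in control library 2, but at 184 in salt-sensitive and 345 in control library 1, and the gluconeogenesis gene Pck1 at 88.9 and 91.1 against 180.3 and 180.2. In cluster 1 the log2 ratios of salt-sensitive over angiotensin II and of control library 1 over control library 2, which share no library, correlated across 5538 genes at 0.106, outside the −0.03 to 0.02 of counts drawn from the pooled profile, which argues against counting noise, although only 54.1% of genes had the same sign. A different proximal and distal makeup stays open, since genes leaning to neither segment still gave 0.115 (0.08 to 0.15), an interval that holds the limit set for this test. A batch shared by 1 hypertension library and 1 control library also stays open. Ratios within the pairs salt-sensitive with control 1 and angiotensin II with control 2 correlated at 0.294, against 0.177 for the other pairing. The larger covariance of the former pairing follows arithmetically from the positive correlation above, so it is no separate evidence. The split could reflect libraries prepared together or the matching controls of each model, which no source used here decides.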
